A study of Homo sapiens with 9 samples.

How the data were processed

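RNA sequencing of primary human hepatocytes from a commercial supplier was analysed in 9 libraries, 3 uncultured, 3 after 36 hours of normoxic culture and 3 after 36 hours at 7% oxygen. Total RNA was extracted with a Nucleospin RNA kit and libraries were made with the NEBNext Ultra II RNA kit, per the labels' protocols. Samples were grouped by their labels, and no sample was left out. The labels give replicate numbers but do not say what a replicate is.

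Reads were trimmed with Trimmomatic, checked with FastQC, aligned with STAR and counted with featureCounts, per the submitters' processing notes, which give no versions. The deposited values are raw counts of read pairs per gene, made with featureCounts 2.0.0 over exons grouped by gene symbol, unstranded, by largest overlap and with no option for multi-mapping reads, per the file headers. The genome build is GRCh38.p14, per the submitters' processing notes. Alignment settings are not given in the sources used here. Each file holds 49677 genes. Gene spans are those of the exons in the files.

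The counts of sense and antisense transcripts are not separated in unstranded libraries. Pairs that map to several places were not counted, so genes with near-identical copies are under-counted. Of 1579 protein-coding genes with a copy on an alternate sequence 77.5% had under 100 counts over all libraries, against 29.7% of the 17936 without. LDHA (21 counts), APOB (24) and ACTG1 (32) are examples and were not tested. Of 44 list members that were not tested 26 have such a copy. Values of the metallothioneins, AKR1C genes, alpha globins, alcohol dehydrogenases and ribosomal proteins share reads between relatives and are uncertain for a single gene.

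Genes were tested with the edgeR 4.0.16 quasi-likelihood test (robust, limma 3.58.1, statmod 1.5.0, R 4.3.3). Library sizes were scaled by TMM, genes were kept by filterByExpr (minimum count 10, total 15), and the model had the 3 groups on all 9 samples with no block. TMM factors were 0.624 to 0.658 in uncultured libraries, 1.29 to 1.40 in normoxia and 1.08 to 1.21 in physioxia. The biological coefficient of variation was 0.138. The 3 pairwise contrasts and the mean of both cultures against uncultured cells were tested with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. A gene or list that was called is said to have risen, fallen or changed. Group levels are means of CPM over TMM-scaled library sizes, while shares of the counts and the floor of 3 counts use the plain library totals. Errors of log2 fold changes are standard errors from the fitted model.

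The 36 gene lists were fixed from general knowledge before the data were examined. Each was tested by camera with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists within a contrast. Beside it stand camera with a correlation estimated from the data, the counts of members past the test, and the same counts adjusted over the list alone. Fry, a second list test, is given for physioxia against normoxia in the part on processing. The comparisons, the tests, the lists, the scalings to be compared and the rule for naming genes were chosen before the data were examined. By that rule the text names genes from the 8 highest and 8 lowest log2 fold changes per contrast (adjusted p under 0.05, at least 5 CPM in the higher group, no overlap between replicates of the 2 groups). It also names up to 4 called members per list with the largest change and a mean of at least 1 CPM (or the 2 most abundant where none passed), and 18 genes fixed by name. With 3 against 3, groups without overlap arise by chance in 10% of genes without a difference. CD163 and CD68 in the oxygen comparison, genes carried from one comparison into another, and the genes drawn in the plots were chosen after their values were seen.

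Nearness to uncultured cells was measured over genes called in both the culture and the oxygen contrast, which are orthogonal. The distance of each cultured library to the uncultured mean used log2 CPM with a prior count of 2. The plan named the Euclidean distance, and it is printed divided by the square root of the number of genes, which leaves the exact permutation test over 20 assignments unchanged. Calls were counted over all other splits of the samples, 10 for each pairwise contrast and 84 for culture against uncultured cells.

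Alternatives chosen before the data were examined were median-ratio, upper quartile and library size scaling, no low-count filter, a filter of 1 CPM in 3 samples, DESeq2 1.42.0, limma-voom, the contrast's samples alone, a replicate block, each library left out, no mitochondrially encoded genes, no 20 most abundant genes, an adjusted p under 0.01 and a test against a 1.5-fold change. For the distance they were a prior count of 0.5 and genes of at least 10 CPM. Of 4 alternatives added after the data were seen 3 remove a GC and length trend, from the tests, from nearness and distance, and from the tests without physioxia 1. For these a natural spline with 3 knots was fitted in each library to GC content of the longest GENCODE v29 transcript and to exon length, over nuclear protein-coding genes with a mean over 5 CPM, and used as an offset. GC values were found for 14465 of the 17494 tested genes. The other leaves out the markers of other cell types. The spread of a list over libraries, also added after the data were seen, is that of the median of its members in each library, with a Welch 95% interval for the difference between groups.

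The tests were tested on simulated data with 50 genes changed at each size. For physioxia against normoxia 4% of genes were recovered at 1.25-fold, 38% at 1.5-fold, 70% at 2-fold and 88% at 4-fold, with 8 false calls among 17494 genes. A simulated GC and length trend gave 207 false calls, and 11 among 14465 genes once it was removed. That trend had the form fitted to these data and was removed by the same spline. Its removal therefore does not show whether the trend in the data is technical. With no list changed 0 of 36 lists were called. Simulated genes were drawn independently, so this says nothing about lists whose members move together. In physioxia against normoxia a correlation of 0.7602 was estimated for the ribosomal protein list.

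Some genes are not reported here. Loading and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.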

Results

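Gene expression was measured by RNA sequencing in primary human hepatocytes, the parenchymal cells of the liver, bought frozen from a commercial supplier. The 9 libraries fall into 3 groups of 3: cells taken straight from the vial (uncultured), cells kept for 36 hours in normoxic culture (normoxia), and cells kept for 36 hours in a culture at 7% oxygen (physioxia). The series concerns control of the oxygen tension that cells meet in culture. The labels do not say whether replicates came from separate vials or cultures. The spread between these 9 samples, against which genes were tested, may therefore be technical. Camera's p-values with the preset correlation compare the genes of a list with all other genes. They do not measure how well the libraries agree on a list. Total counts per library were 48862357, 30443530 and 35457002 for uncultured replicates 1 to 3. They were 33983606, 28885353 and 28137182 for normoxia, and 46846575, 20743502 and 29365486 for physioxia. A gene with 0 counts in a library could therefore have a level of up to 0.0614 to 0.145 CPM (counts scaled to library size, here the plain library total), a floor of 3 counts that covers counting error only.

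The uncultured libraries stood far from both cultured groups on the first principal component, which held 78.4% of the variance, and normoxia and physioxia parted on the second, which held 7.98%. ALB, the gene of serum albumin, took 9.09% ± 0.250 of the counts in uncultured cells (SD, n = 3), 3.26% ± 0.352 in normoxia and 3.49% ± 0.178 in physioxia. Messenger RNAs encoded by mitochondrial DNA took 13.2% ± 0.566 of the counts in uncultured cells, 4.31% ± 0.185 in normoxia and 5.95% ± 0.668 in physioxia. Mitochondrial ribosomal RNAs took 2.44% ± 0.083, 6.49% ± 0.949 and 9.86% ± 1.28 (n = 3 each). Replicates differed by more than counting noise in every pair, with chi-square per degree of freedom from 6.86 to 62.8. Physioxia 1 stood apart from physioxia 2 (49.0) and physioxia 3 (62.8), which differed less from each other (9.10). It also parted from them on the third component, which held 4.27%.

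**Figure D1:**
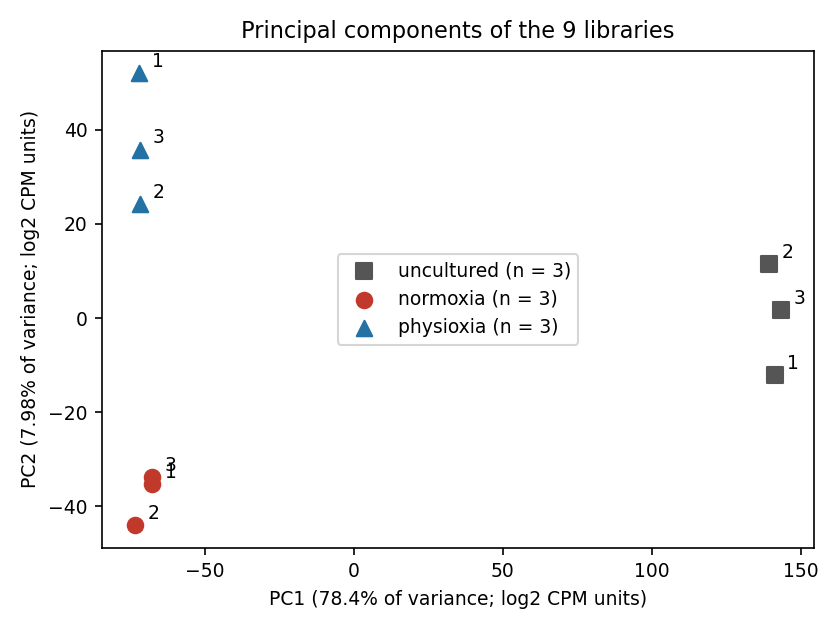
Scores of the 9 libraries on the first and second principal components of log2 CPM, with the share of variance on each axis and the replicate number beside each symbol. The 3 uncultured libraries lie at one end of the first component (78.4% of variance), and the normoxia and physioxia libraries separate on the second (7.98%).

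The oxygen comparison, physioxia against normoxia, sets together cells cultured for the same time under different oxygen. Of 40 genes induced through hypoxia-inducible factor (HIF), the oxygen-regulated transcription factor, 20 were lower and 3 higher in physioxia. Among the lower was VEGFA, the angiogenic growth factor, at 434 ± 86.6 CPM in normoxia and 197 ± 9.18 in physioxia (SD, n = 3), a log2 fold change of -1.14 ± 0.14 (SE). Of 31 phase I drug metabolism genes 15 were higher and 3 lower, among the higher POR, the reductase that feeds electrons to cytochrome P450 enzymes, at 153 ± 5.03 and 390 ± 58.0 CPM with a log2 fold change of 1.35 ± 0.11. Most markers of macrophages and red cells and some of lymphocytes were higher as well, with the macrophage receptor gene VSIG4 at 0.418 ± 0.122 and 6.99 ± 2.73 CPM. The gene for the insulin-like growth factor binding protein IGFBP3 had the lowest log2 fold change among the named genes, -2.44 ± 0.16, from 169 ± 35.0 to 31.2 ± 2.58 CPM. In GRCh38.p14 the exons of VEGFA span chromosome 6 from 43770209 to 43786487 and those of POR chromosome 7 from 75915155 to 75986855. Those of VSIG4 span chromosome X from 66021738 to 66040080 and those of IGFBP3 chromosome 7 from 45912245 to 45921272.

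Of 17494 genes tested, 3442 differed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 2043 higher and 1399 lower in physioxia, which makes 59.4% of them higher. A log2 fold change of at least 1 in size was found for 274 of the higher and 385 of the lower genes. The balance moved with the scaling between libraries. Upper quartile scaling called 1642 higher and 1728 lower. Scaling by library size alone, which shifts the median of all genes by -0.22 on the log2 scale, called 778 higher and 3198 lower. The fold changes also followed base composition and exon length across 9190 expressed protein-coding genes (genes are not independent replicates). Their Spearman correlation was 0.538 with GC content and -0.493 with exon length. Within the physioxia group physioxia 1 leaned the same way against physioxia 2 and 3 (0.497 and -0.495). After that trend was removed from each library, 2118 of 14465 genes differed, 1019 higher and 1099 lower. Of the 3442 genes called without the correction 3217 were among those 14465, and 1497 of them were called in the same direction with it. Leaving out normoxia 1 or normoxia 2 gave 2053 and 1563 genes, and leaving out physioxia 1 gave 3257.

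Among 40 tested HIF targets, 20 fell, 3 rose and 17 did not pass the test in physioxia against normoxia (23 lower and 3 higher adjusted over the list alone), with a median log2 fold change of -0.50. The list was called lower by camera, a test of a list against all other genes (adjusted p = 2.97e-09; adjusted p = 0.37 with an estimated correlation). LOX, a collagen-crosslinking enzyme, fell by 1.83 ± 0.22 on the log2 scale, the glycolytic regulator PFKFB4 by 1.61 ± 0.26, the oxygen-sensing prolyl hydroxylase EGLN3 by 1.60 ± 0.30 and the mitophagy receptor BNIP3L by 1.36 ± 0.16 (SE, n = 3 against 3). VEGFA fell (adjusted p = 0.000175, edgeR quasi-likelihood test), and so did NDRG1 (-0.73 ± 0.15, 680 ± 178 to 409 ± 37.1 CPM). Not every classical target moved. CA9, a carbonic anhydrase, had a log2 fold change of -0.50 ± 0.24 (adjusted p = 0.156, edgeR) and ANKRD37 of -0.25 ± 0.19 (adjusted p = 0.397, edgeR). With the GC and length trend removed the list's median was -0.49, with 24 lower and 3 higher. CA9 then passed the test (-0.92, edgeR adjusted p = 0.0166), as it did under library size scaling (-0.73). The median was negative under all 3 other scalings. Of 18 tested glycolysis genes 1 fell and 17 did not pass (0 adjusted over the list alone), and the list was not called (median -0.07, camera adjusted p = 0.378). The gene that fell was SLC16A3, a lactate exporter (-0.80 ± 0.24). Its call was lost without uncultured 3 (-0.80), normoxia 2 (-0.80), normoxia 3 (-0.53), physioxia 1 (-0.82) or physioxia 3 (-0.68), and after the trend was removed (-0.93). The glycolysis list was called lower after the trend was removed (0 of 18 higher, 6 lower, median -0.26, camera adjusted p = 0.00239; adjusted p = 0.3635 with an estimated correlation) and without normoxia 1 (camera adjusted p = 0.0307).

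**Figure D2:**
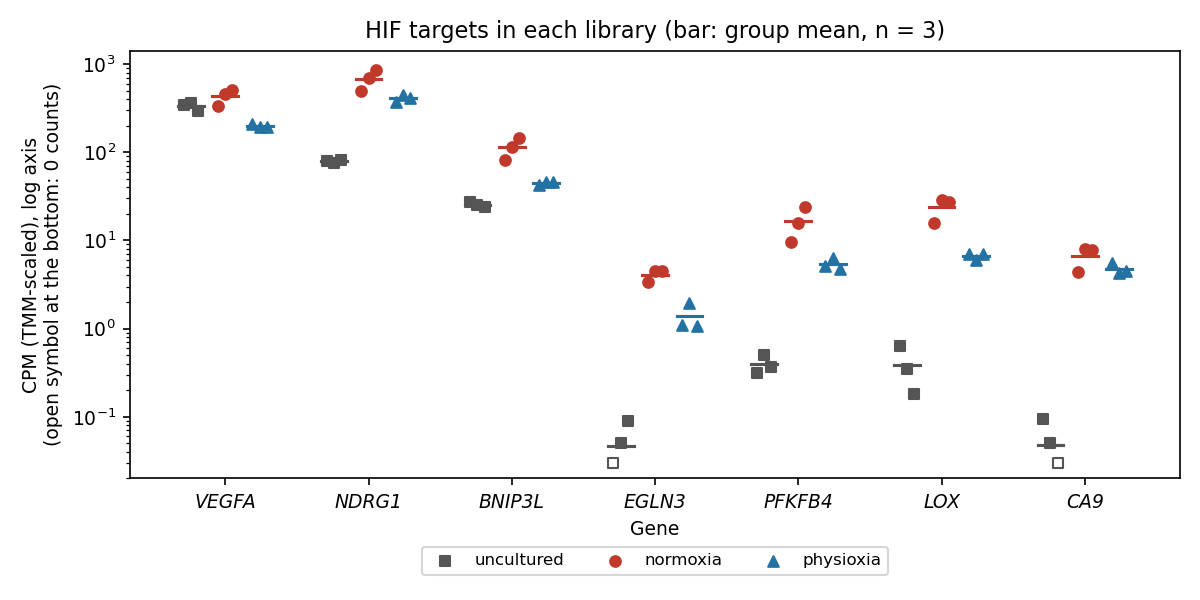
Levels of 7 HIF targets in each library (CPM on a log axis, 1 symbol per library, bars at the group means, n = 3, open symbols at the bottom for 0 counts). For VEGFA, NDRG1, BNIP3L, EGLN3, PFKFB4 and LOX the 3 physioxia libraries lie below the 3 normoxia libraries. Mean levels of VEGFA were 434 CPM in normoxia and 197 in physioxia.

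Phase I drug metabolism genes, mainly cytochrome P450 enzymes, were called higher in physioxia (median log2 fold change 0.32, camera adjusted p = 1.9e-07; adjusted p = 0.237 with an estimated correlation). Of 31 tested members 15 rose, 3 fell and 13 did not pass (16 higher and 3 lower adjusted over the list alone). CYP1A2 rose by 1.35 ± 0.18 on the log2 scale, CYP2B6 by 1.05 ± 0.11 from 125 ± 6.01 to 258 ± 29.2 CPM, and CYP3A4, which metabolises many drugs, by 0.54 ± 0.12 from 217 ± 30.6 to 316 ± 27.2 CPM. With the GC and length trend removed, 9 rose and 2 fell, with a median of 0.24 (camera adjusted p = 1.21e-07; adjusted p = 0.265 with an estimated correlation). Phase II conjugation genes were not called (4 of 18 higher, 1 lower, the same counts adjusted over the list alone, median 0.17, camera adjusted p = 0.192, or 0.0471 and called higher with no low-count filter). UGT2B4, a glucuronosyltransferase, fell (-0.45 ± 0.10). Under library size scaling the phase II median was -0.05. Hepatic transporters had 1 of 18 higher and 4 lower (2 and 4 adjusted over the list alone, median -0.07, camera adjusted p = 0.436). The anion transporter SLCO1B1 fell (-0.59 ± 0.10).

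Genes of secreted plasma proteins were called higher in physioxia (median 0.42, camera adjusted p = 1.07e-09; adjusted p = 0.37 with an estimated correlation). Of 38 tested, 20 rose and 2 fell (21 and 2 adjusted over the list alone). Among those that rose were RBP4, the retinol carrier, by 0.87 ± 0.14 from 1674 ± 238 to 3067 ± 358 CPM, and the clotting factor gene F12 by 0.80 ± 0.12 (0.46 and 0.41 with the GC and length trend removed). ALB itself did not pass (0.31 ± 0.15, adjusted p = 0.153, edgeR). Once the GC and length trend was removed the median was 0.25, with 11 higher and 1 lower. Acute phase proteins had a median of 0.42 with 8 of 17 higher and 0 lower (11 and 1 adjusted over the list alone, camera adjusted p = 2.19e-05; adjusted p = 0.37 with an estimated correlation). After the trend was removed 1 was higher, with a median of 0.15, and camera's call was lost when physioxia 1 was left out too (adjusted p = 0.0504). Hepatocyte transcription factors divided, 4 of 19 higher and 4 lower (5 and 5 adjusted over the list alone, median -0.15, camera adjusted p = 0.393, or 0.0341 and called lower with the GC and length trend removed and physioxia 1 left out). With the trend removed 2 were higher and 6 lower, and with physioxia 1 left out too 2 and 7. HNF4A, a master regulator of hepatocyte identity, rose by 0.36 ± 0.09 (a call lost under library size scaling), while NR5A2 (-0.79 ± 0.10) and PROX1 (-0.74 ± 0.10) fell.

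Urea cycle genes, which detoxify ammonia, were called higher (4 of 10 higher, 0 lower, 5 and 0 adjusted over the list alone, median 0.30, camera adjusted p = 0.00192; adjusted p = 0.231 with an estimated correlation). NAGS rose by 0.89 ± 0.11 and ASL by 0.69 ± 0.11 (0.50 and 0.35 with the trend removed). After removal of the GC and length trend 3 were higher, with a median of 0.15. Genes of the periportal zone of the liver lobule, the zone nearest the oxygen-rich inflow, were called higher (4 of 13 higher, 1 lower, 5 and 1 adjusted over the list alone, median 0.29, camera adjusted p = 0.0123; adjusted p = 0.487 with an estimated correlation). PIGR, the receptor that carries immunoglobulin A into bile, rose by 1.18 ± 0.10, and the serine dehydratase SDS rose by 1.07 ± 0.14. The periportal call was lost without normoxia 2 (median 0.165, 2 higher and 2 lower, camera adjusted p = 0.119) or physioxia 3 (0.20, 0.0543) and under limma-voom (0.30, 0.0561). With the trend removed 3 of 12 were higher and 1 lower, with a median of 0.15 (camera adjusted p = 0.00762; adjusted p = 0.386 with an estimated correlation). Pericentral genes had 5 of 16 higher and 5 lower, the same adjusted over the list alone (median 0.10, or -0.13 under library size scaling, camera adjusted p = 0.644). Among them CYP1A2 was higher and the xenobiotic receptor gene AHR lower (-0.65 ± 0.12). Gluconeogenesis genes were not called (2 of 15 higher, 2 lower, 3 and 2 adjusted over the list alone, median 0.18, or -0.03 under library size scaling, camera adjusted p = 0.497). SDS rose and the glycogen phosphorylase gene PYGL fell (-0.66 ± 0.11). G6PC1 and PCK1, enzymes of glucose production, did not pass (-0.23 ± 0.12 and -0.27 ± 0.15). PCK1 passed as lower under library size scaling (-0.47) or without normoxia 2 (-0.44), and G6PC1 under library size scaling (-0.45). Bile acid synthesis had 3 of 12 higher and 1 lower (4 and 1 adjusted over the list alone, median 0.01, or -0.22 under library size and -0.03 under upper quartile scaling, camera adjusted p = 0.436). SLC27A5 rose (0.78 ± 0.12) and CYP7B1 fell (-0.68 ± 0.12, or -0.39 with the trend removed), while CYP7A1, the rate-limiting enzyme, did not pass (0.02 ± 0.26, of the opposite sign under library size scaling).

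Genes of fatty acid oxidation were called higher in physioxia (10 of 24 higher, 1 lower, 11 and 1 adjusted over the list alone, median 0.26, camera adjusted p = 0.000266; adjusted p = 0.366 with an estimated correlation). CPT1A, the gate of fatty acid entry into mitochondria, rose by 1.00 ± 0.11 from 17.8 ± 2.60 to 35.7 ± 1.08 CPM and the lipid droplet protein PLIN2 by 0.97 ± 0.10. After the GC and length trend was removed 7 were higher and 0 lower, with a median of 0.15. Fatty acid synthesis was not called (2 of 16 higher, 1 lower, 3 and 2 adjusted over the list alone, median -0.01, of the opposite sign under median-ratio scaling, camera adjusted p = 0.525). Even so SCD, which makes monounsaturated fatty acids, fell by 1.13 ± 0.12 from 868 ± 150 to 397 ± 27.3 CPM. Cholesterol synthesis was not called either (5 of 24 higher, 1 lower, 6 and 1 adjusted over the list alone, median 0.05, or -0.16 under library size scaling, camera adjusted p = 0.378). With the trend removed 1 was higher and 1 lower, with a median of -0.06. MVD was higher (0.48 ± 0.10), a call lost under library size scaling (0.26) and after the trend was removed (0.09). STARD4, a sterol carrier, was lower (-0.59 ± 0.13, or -0.36 with the trend removed).

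The 13 transcripts of the mitochondrial genome for respiratory chain subunits had a median log2 fold change of 0.67, with 10 higher and 0 lower (12 and 0 adjusted over the list alone, camera adjusted p = 2.74e-13; adjusted p = 0.231 with an estimated correlation). The mitochondrially encoded COX2 rose by 1.23 ± 0.14 from 871 ± 3.79 to 2048 ± 426 CPM and ND3 by 1.13 ± 0.18. After removal of the GC and length trend 10 were higher, with a median of 0.38. Nuclear genes of the respiratory chain were called higher (25 of 65 higher, 0 lower, 30 and 0 adjusted over the list alone, median 0.35, camera adjusted p = 5.02e-09; adjusted p = 0.487 with an estimated correlation). After that removal 8 were higher, with a median of 0.10, and the list was still called higher (camera adjusted p = 0.00762; adjusted p = 0.386 with an estimated correlation), though not when physioxia 1 was also left out (camera adjusted p = 0.101). NDUFS7, a subunit of complex I, stood at 0.76 ± 0.11 and after removal at 0.43. Genes of cytosolic ribosomal proteins, short and GC-rich, had 21 of 67 higher and 0 lower (30 and 1 adjusted over the list alone, median 0.31, camera adjusted p = 2.16e-09; adjusted p = 0.49 with an estimated correlation). After removal 4 were higher and 3 lower, with a median of 0.04 and no camera call (adjusted p = 0.206). RPL35 stood at 0.66 ± 0.15 before and 0.05 after.

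**Figure D3:**
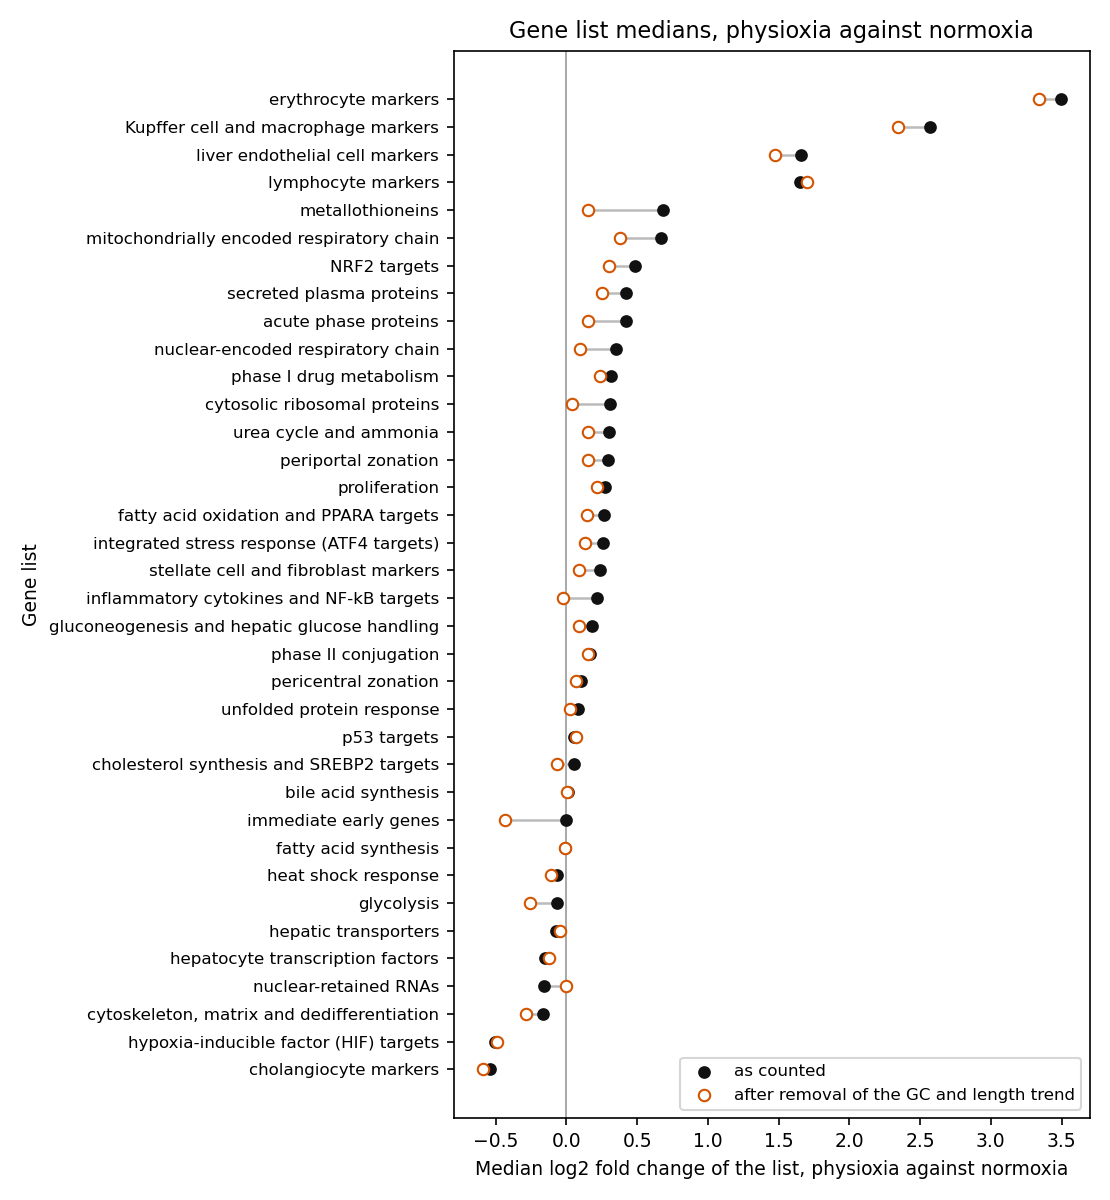
Median log2 fold change, physioxia against normoxia, of the 36 gene lists, with filled symbols for the counts as deposited and open symbols for values after the GC and length trend was removed from each library. The medians of the HIF targets (-0.50 and -0.49) and of the macrophage markers (2.57 and 2.35) lie far apart from those of the ribosomal proteins, which go from 0.31 to 0.04.

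NRF2 targets, which answer oxidative and electrophilic stress, were called higher in physioxia (10 of 22 higher, 1 lower, 11 and 1 adjusted over the list alone, median 0.48, camera adjusted p = 1.9e-07; adjusted p = 0.137 with an estimated correlation). AKR1C1, an aldo-keto reductase with close paralogs, rose by 1.05 ± 0.12. With the GC and length trend removed 9 were higher and 1 lower, with a median of 0.30. Targets of ATF4, the integrated stress response factor, were called higher (8 of 25 higher, 0 lower, 9 and 0 adjusted over the list alone, median 0.26, camera adjusted p = 4.24e-05; adjusted p = 0.137 with an estimated correlation). The glutathione-degrading CHAC1 rose by 1.02 ± 0.16 and the stress cytokine GDF15 by 0.85 ± 0.13 (0.55 and 0.39 with the trend removed). After the removal 7 were higher and 1 lower, with a median of 0.13. Metallothioneins, metal-binding proteins whose genes are near-identical, had 7 of 8 higher (8 adjusted over the list alone, median 0.68, camera adjusted p = 5.38e-05; adjusted p = 0.37 with an estimated correlation). After removal 1 of 8 was higher, with a median of 0.15 and no camera call (adjusted p = 0.0697). MT2A stood at 0.80 ± 0.20, a call lost without normoxia 1 (0.73) or normoxia 2 (0.71) and after removal (0.28). The unfolded protein response was not called (2 of 19 higher, 1 lower, the same adjusted over the list alone, median 0.08, or -0.12 under library size scaling, camera adjusted p = 0.378). SDF2L1 was higher (0.90 ± 0.11), a call lost after removal (0.35). Heat shock genes were not called (2 of 12 higher, 2 lower, 2 and 4 adjusted over the list alone, median -0.07, camera adjusted p = 0.525). The inducible chaperone HSPA6 nevertheless fell by 1.03 ± 0.15 from 1590 ± 228 to 778 ± 156 CPM and DNAJB1 by 0.60 ± 0.12. After the trend was removed the heat shock list was called lower (median -0.11, camera adjusted p = 0.0386; adjusted p = 0.3635 with an estimated correlation). p53 targets had 3 of 16 higher and 3 lower (4 and 3 adjusted over the list alone, median 0.05, or -0.16 under library size scaling, camera adjusted p = 0.623). TP53INP1 was lower (-0.48 ± 0.10, or -0.24 with the trend removed).

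Genes of the cytoskeleton, matrix and dedifferentiation, which hepatocytes raise on plastic, were called lower in physioxia (0 of 36 higher, 9 lower, the same adjusted over the list alone, median -0.17, camera adjusted p = 0.00192; adjusted p = 0.49 with an estimated correlation). The integrin gene ITGAV fell by 1.02 ± 0.17, the fibronectin gene FN1 by 0.90 ± 0.16 and VIM, a mesenchymal filament, by 0.61 ± 0.14. ACTB did not pass (0.01 ± 0.11), with negative values under upper quartile (-0.03) and library size scaling (-0.21). With the GC and length trend removed, 9 were lower with a median of -0.29, and ACTB passed as lower (-0.32). Immediate early genes were called lower (1 of 16 higher, 4 lower, 1 and 5 adjusted over the list alone, mean -0.25, camera adjusted p = 0.0286; adjusted p = 0.49 with an estimated correlation). FOS fell by 1.07 ± 0.14, FOSB by 1.03 ± 0.16 and EGR1 by 0.90 ± 0.13. The list's median, -0.005, was of the opposite sign under median-ratio scaling, and its call was lost without normoxia 3 (camera adjusted p = 0.133) or physioxia 2 (0.154) and under limma-voom (0.125). With the GC and length trend gone 0 were higher and 7 lower, with a median of -0.44 (camera adjusted p = 1.67e-06; adjusted p = 0.265 with an estimated correlation). NF-kB targets were not called (3 of 19 higher, 3 lower, the same adjusted over the list alone, median 0.22, or -0.01 under library size scaling and -0.03 with the GC and length trend removed, camera adjusted p = 0.562). The neutrophil chemokine CXCL2 fell by 1.12 ± 0.18 and CCL20 rose by 0.74 ± 0.15. CXCL10 (3.44 ± 0.82) rose beside the macrophage markers, a call lost without normoxia 1, 2 or 3 (3.56, 3.31 and 3.46), with a value of 2.44 without physioxia 2. Proliferation genes were rare and called slightly higher by camera (median 0.27, adjusted p = 0.0204; adjusted p = 0.231 with an estimated correlation). Of 21 members 1 was higher and 0 lower, 0 adjusted over the list alone and 0 after the trend was removed (camera adjusted p = 0.0578). Camera's call was also lost without physioxia 3 (adjusted p = 0.0645) and under a filter of 1 CPM in 3 samples (0.0637). Its cell-cycle marker MKI67 did not pass (2.02 ± 1.03, adjusted p = 0.2, edgeR), but did without physioxia 1 (2.63). Nuclear-retained RNAs were not called (0 of 7 higher, 1 lower, the same adjusted over the list alone, median -0.16, camera adjusted p = 0.525). The imprinted MEG3 was lower (-2.13 ± 0.49).

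Markers of other liver cell types moved with the oxygen groups too, at levels mostly under 50 CPM. Of 14 tested markers of Kupffer cells and macrophages 12 rose and 0 fell in physioxia (13 and 0 adjusted over the list alone, median 2.57, camera adjusted p = 4.01e-25; adjusted p = 0.0852 with an estimated correlation). CD163 went from 4.54 to 26.2 CPM and C1QA from 0.323 ± 0.159 to 3.95 ± 1.48 CPM. CD68, at 200 CPM in normoxia, rose by 0.53. Endothelial markers were called higher (5 of 12 higher, 0 lower, 6 and 1 adjusted over the list alone, median 1.66, or 0.98 without physioxia 2, camera adjusted p = 0.00383; adjusted p = 0.237 with an estimated correlation). The scavenger receptor STAB1, which macrophages also express, went from 0.672 ± 0.206 to 12.1 ± 9.71 CPM (log2 4.12 ± 0.59, or 3.25 without physioxia 2). Lymphocyte markers had 4 of 10 higher and 0 lower (8 and 0 adjusted over the list alone, median 1.65, camera adjusted p = 4.93e-05; adjusted p = 0.0852 with an estimated correlation). The interleukin receptor IL7R rose by 2.89 ± 0.33. All 7 tested red cell markers rose, also adjusted over the list alone (median 3.50, or 4.25 without normoxia 3, camera adjusted p = 9.47e-15; adjusted p = 0.0852 with an estimated correlation). The globin HBB went from 3.80 ± 2.92 to 42.1 ± 16.3 CPM (log2 3.50 ± 0.55, or 4.31 without normoxia 3). Cholangiocyte markers went the other way (1 of 10 higher, 3 lower, 1 and 4 adjusted over the list alone, median -0.54, camera adjusted p = 0.0446; adjusted p = 0.315 with an estimated correlation). EPCAM (-1.54 ± 0.29) and CD24 (-0.70 ± 0.12) were lower. Their call was lost under upper quartile (camera adjusted p = 0.0538) and library size scaling (0.0887) and without normoxia 1 (0.143), physioxia 1 (0.154), physioxia 2 (0.076) or physioxia 3 (0.106), under limma-voom (0.0712), and with the GC and length trend removed and physioxia 1 left out (0.145). Stellate cell markers were not called (1 of 11 higher, 0 adjusted over the list alone, median 0.24, camera adjusted p = 0.525). After removal of the GC and length trend the macrophage list had 11 higher with a median of 2.35, and the red cell list 7 with 3.34. Leaving all members of these 6 lists out of library sizes and tests gave 3420 changed genes. That step kept 17430 of the 17494 genes, so the count could hardly move. It does not show whether the differences between the cultures depend on RNA of other cell types.

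**Figure D4:**
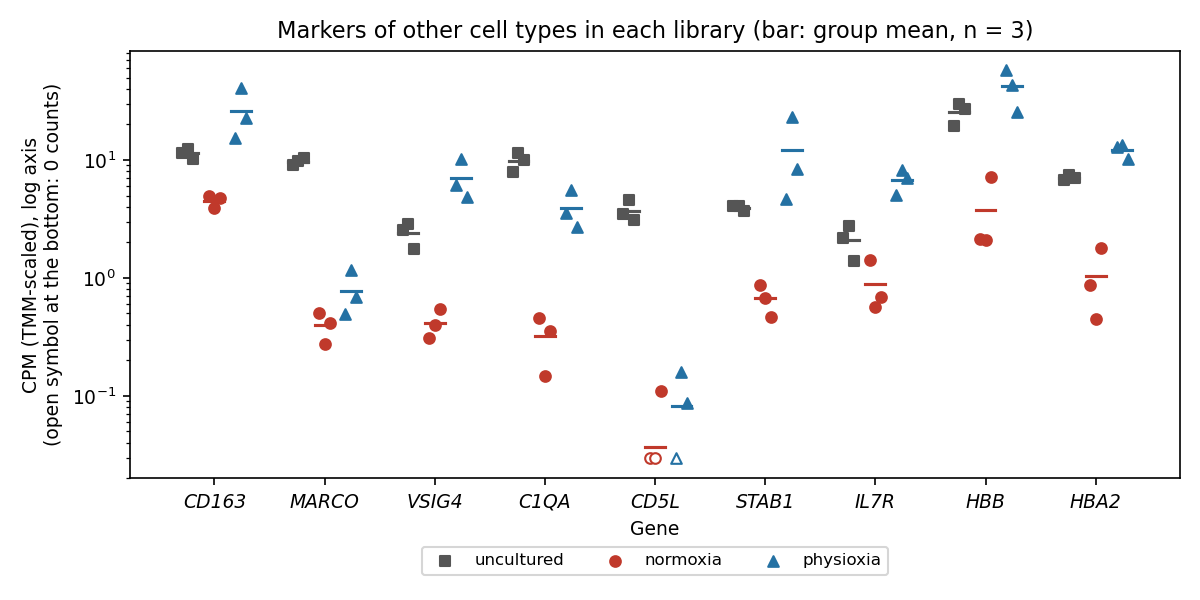
Levels of 9 markers of macrophages, endothelial cells, lymphocytes and red cells in each library (CPM on a log axis, 1 symbol per library, bars at the group means, n = 3, open symbols at the bottom for 0 counts). HBB averaged 25.6 CPM in uncultured cells, 3.80 in normoxia and 42.1 in physioxia, while MARCO averaged 9.67, 0.397 and 0.781.

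The comparison of normoxia with uncultured cells shows the change over 36 hours in normoxic culture. Genes of hepatocyte function fell nearly throughout, with ALB at 141400 ± 5981 CPM in uncultured cells and 24390 ± 3525 in normoxia (SD, n = 3; log2 -2.54 ± 0.16). CPS1, the first enzyme of the urea cycle, went from 4299 ± 139 to 127 ± 18.8 CPM (-5.08 ± 0.15). Genes of the cytoskeleton and matrix rose, with the actin crosslinker FLNA at 17.9 ± 4.44 and 1142 ± 199 CPM. Many HIF targets rose, with NDUFA4L2 at 0.832 ± 0.0439 and 137 ± 39.9 CPM (7.35 ± 0.25). The exons of ALB span chromosome 4 from 73404287 to 73421482, those of CPS1 chromosome 2 from 210477685 to 210679107 and those of the respiratory chain subunit homologue NDUFA4L2 chromosome 12 from 57234903 to 57240762 (GRCh38.p14). In all, 12065 of 17494 genes (69.0%) differed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 6425 higher and 5640 lower, with a log2 fold change of at least 1 in size for 3925 and 3676 of them. Scaling by library size alone shifts the median of all genes by 1.06 and called 11521 higher and 2373 lower.

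In normoxic culture the lists of hepatocyte function were called lower by camera, also with an estimated correlation. Of the phase I genes 0 rose and 30 of 31 fell (median -3.32, camera adjusted p = 2.35e-37; adjusted p = 0.0104 with an estimated correlation), among them ADH1B, an alcohol dehydrogenase (-4.90 ± 0.17), and CYP3A4 (-3.79 ± 0.13). All 18 phase II genes fell (median -2.89, camera adjusted p = 1.08e-19; 0.0215 with an estimated correlation). Transporters had 17 of 18 lower and 1 higher (median -2.84, camera adjusted p = 2.05e-19). All 38 plasma protein genes fell (median -2.92, camera adjusted p = 2.35e-37), among them the complement gene C5 (-4.45 ± 0.17). All 17 acute phase genes fell too (median -2.56, camera adjusted p = 1.66e-15), among them C3 (-4.39 ± 0.14). All 19 transcription factors fell (median -2.13, camera adjusted p = 1.13e-13), among them the estrogen receptor gene ESR1 (-4.77 ± 0.11) and HNF4A (-2.18 ± 0.09). In the next lists the pair in brackets gives the median log2 fold change and camera's adjusted p. Urea cycle genes had 9 of 10 lower and 1 higher (-2.79, 2.21e-10), bile acid genes 11 of 12 lower and 1 higher (-3.44, 1.79e-14), and gluconeogenesis genes 15 of 15 lower (-3.41, 1.19e-16). Fatty acid oxidation had 21 of 24 lower and 2 higher (-2.48, 2.2e-18), periportal genes 13 of 13 lower (-3.41, 1.59e-18) and pericentral genes 13 of 16 lower and 2 higher (-2.95, 2.66e-09). The unfolded protein response fell in 18 of 19 (median -1.50, camera adjusted p = 4.45e-09), in the chaperone gene HSP90B1 by 2.21 ± 0.12. Adjusted over the list alone, the counts in this comparison were the same for every list except the ATF4 targets (13 higher, 8 lower), NRF2 targets (18 and 3), metallothioneins (4 and 3) and ribosomal proteins (34 and 0).

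All 13 mitochondrially encoded genes fell in normoxia against uncultured cells (median -2.33, camera adjusted p = 5.9e-14; adjusted p = 0.0815 with an estimated correlation), COX1 from 65600 ± 1415 to 5130 ± 280 CPM. Nuclear genes of the respiratory chain had 0 of 65 higher and 52 lower (median -0.65, camera adjusted p = 0.000297; adjusted p = 0.534 with an estimated correlation). Library size scaling instead gave 43 higher, 3 lower, a median of 0.41 and no camera call (adjusted p = 0.137). Ribosomal protein genes had 35 of 67 higher and 0 lower (median 0.36, camera adjusted p = 0.0236; adjusted p = 0.722 with an estimated correlation), RPL8 rising by 0.93 ± 0.11. The call was lost without uncultured 1 (camera adjusted p = 0.0551). Cholesterol synthesis (8 of 24 higher, 11 lower, median -0.02, or 1.04 under library size scaling, camera adjusted p = 0.446) and fatty acid synthesis (6 of 16 higher, 7 lower, median -0.09, or 0.97, camera adjusted p = 0.628) divided. SQLE rose by 2.28 ± 0.13 and INSIG1 fell (-2.12 ± 0.10). FADS1 and ACLY rose by 2.84 ± 0.10 and 2.78 ± 0.11 and the lipogenic regulator MLXIPL fell (-2.85 ± 0.15).

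HIF targets had 29 of 40 higher and 6 lower in normoxia against uncultured cells (median 1.59, camera adjusted p = 4.94e-08; adjusted p = 0.273 with an estimated correlation). The hormone gene STC2 rose by 7.20 ± 0.16 and NDRG1 by 3.11 ± 0.16. CA9 and EGLN3, at 0.0482 and 0.0468 CPM in uncultured cells, below the floor of a single library, reached 6.73 ± 2.02 and 4.10 ± 0.619 CPM. VEGFA rose by 0.37 ± 0.13, a call lost without uncultured 3 (0.29), normoxia 2 (0.34) or normoxia 3 (0.26). Glycolysis genes had 14 of 18 higher and 4 lower (median 1.83, camera adjusted p = 1.05e-06; adjusted p = 0.11 with an estimated correlation). The kinases PFKP and PKM rose by 5.94 ± 0.19 and 4.22 ± 0.15. Cytoskeleton and matrix genes had 33 of 36 higher and 1 lower (median 3.29, camera adjusted p = 2.1e-27; 0.024 with an estimated correlation). VIM rose by 4.28 ± 0.16 and ACTB by 2.80 ± 0.12. The pairs in brackets again give the median and camera's adjusted p. NF-kB targets had 15 of 19 higher and 2 lower (2.49, 1.9e-07), CCL20 rising by 5.83 ± 0.22. Heat shock genes had 11 of 12 higher and 1 lower (1.06, 0.000153; adjusted p = 0.115 with an estimated correlation), HSPA6 rising by 5.23 ± 0.18. p53 targets had 12 of 16 higher and 3 lower (1.12, 6.98e-05), AEN rising by 3.86 ± 0.11. NRF2 targets had 17 of 22 higher and 3 lower (1.16, 6.5e-05; adjusted p = 0.103 with an estimated correlation), the heme oxygenase HMOX1 rising by 4.03 ± 0.19 and TXNRD1 by 3.78 ± 0.16. ATF4 targets had 13 of 25 higher and 7 lower (0.41, 0.00364; adjusted p = 0.115 with an estimated correlation), GDF15 by 3.77 ± 0.15, and lost the call under limma-voom (0.187). Immediate early genes had 9 of 16 higher and 3 lower (0.46, 0.0187; adjusted p = 0.3 with an estimated correlation), MYC by 2.53 ± 0.11, and lost the call under limma-voom (0.0879). Metallothioneins (4 of 8 higher, 2 lower, median 0.29, camera adjusted p = 0.808), proliferation genes (9 of 21 higher, 5 lower, 0.54, 0.307) and nuclear-retained RNAs (4 of 7 higher, 2 lower, 0.58, 0.139) were not called.

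Markers of other cell types mostly fell in normoxia against uncultured cells. Macrophage markers had 13 of 14 lower and 1, CD68, higher (median -2.58, camera adjusted p = 0.000718; adjusted p = 0.268 with an estimated correlation), MARCO by 4.58 ± 0.29. Endothelial markers had 0 of 12 higher and 9 lower (median -2.75, camera adjusted p = 0.0254; adjusted p = 0.219 with an estimated correlation), OIT3 by 3.07 ± 0.14. Their call was lost with the GC and length trend removed (camera adjusted p = 0.0587) and under the filter of 1 CPM in 3 samples (0.0525). Lymphocyte markers had 0 of 10 higher and 5 lower (median -1.23, camera adjusted p = 0.0299; adjusted p = 0.165 with an estimated correlation), IGKC, the immunoglobulin kappa constant region, from 30.6 ± 3.63 to 0.221 ± 0.121 CPM. Their camera call was lost without uncultured 2 (adjusted p = 0.0552, median -0.59), normoxia 2 (0.0522, median -0.70) or physioxia 1 (0.0528), with the GC and length trend removed (0.067) and under limma-voom (0.0895). All 7 red cell markers were lower (median -2.78, camera adjusted p = 0.033; adjusted p = 0.398 with an estimated correlation), with a median of -3.38 without uncultured 1 and -3.70 without normoxia 3, and the call was lost without physioxia 1 (camera adjusted p = 0.0783). It was also lost with the GC and length trend removed (camera adjusted p = 0.067), under a filter of 1 CPM in 3 samples (0.0774) and on the samples of the contrast alone (0.0939). Cholangiocyte markers had 8 of 10 higher and 2 lower (median 3.18, camera adjusted p = 0.0205; adjusted p = 0.17 with an estimated correlation, and by camera 0.0931 under library size scaling and 0.0742 under limma-voom), the keratin gene KRT7 rising by 6.41 ± 0.31. Stellate markers had 4 of 11 higher and 5 lower (median -0.32, or 0.73 under library size scaling, camera adjusted p = 0.804).

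The comparison of physioxia with uncultured cells shows the change over the same time in culture at 7% oxygen. ALB fell by 2.23 ± 0.15 on the log2 scale to 30240 ± 2493 CPM (SD, n = 3), and CPS1 (-5.14 ± 0.15) and CYP3A4 (-3.25 ± 0.13) fell too. The p53-induced SFN, from 0.487 ± 0.242 to 122 ± 20.9 CPM (7.99 ± 0.30), was among the genes that rose most. STC2 rose by 7.21 ± 0.16, while VEGFA was lower than in uncultured cells (-0.77 ± 0.13, but 0.08 under library size scaling). In all, 12309 of 17494 genes (70.4%) differed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 6453 higher and 5856 lower, of which 4049 and 3901 by a log2 fold change of at least 1. Library size scaling shifts the median of all genes by 0.84 and called 10562 higher and 2868 lower.

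Hepatocyte lists were again called lower. Camera with an estimated correlation kept its call for phase I (30 of 31 lower, 1 higher, median -2.92, camera adjusted p = 3.11e-30), phase II (18 of 18 lower, -2.90, 3.7e-18), transporters (17 of 18 lower, 1 higher, -3.15, 8.35e-20) and transcription factors (18 of 19 lower, 0 higher, -2.23, 7.29e-14). It also kept it for gluconeogenesis (15 of 15 lower, -3.12, 9.4e-16), bile acid synthesis (11 of 12 lower, 1 higher, -2.87, 7.39e-14), the urea cycle (9 of 10 lower, 1 higher, -2.41, 3.92e-08), periportal genes (13 of 13 lower, -3.17, 6.89e-16) and fatty acid oxidation (21 of 24 lower, 3 higher, -2.38, 7.21e-15). It lost the call for plasma proteins (37 of 38 lower, median -2.39, camera adjusted p = 2.27e-29; adjusted p = 0.0751 with an estimated correlation), acute phase proteins (16 of 17 lower, -2.13, 4.41e-12; adjusted p = 0.0846 with an estimated correlation) and pericentral genes (13 of 16 lower, 2 higher, -2.55, 4.62e-09; adjusted p = 0.0504 with an estimated correlation). It also lost it for the unfolded protein response (17 of 19 lower, -1.50, 2.99e-08; adjusted p = 0.0504 with an estimated correlation) and mitochondrially encoded genes (13 of 13 lower, -1.74, 1.19e-08; adjusted p = 0.144 with an estimated correlation). Among the genes that fell were ADH1B (-5.07 ± 0.17), ESR1 (-5.37 ± 0.12), HNF4A (-1.81 ± 0.09), C3 (-3.95 ± 0.14) and COX1 (-3.33 ± 0.13). Adjusted over the list alone, the counts in this comparison were the same for every list except the HIF targets (25 higher, 11 lower), transcription factors (0 and 19), cholesterol synthesis (9 and 12), NRF2 targets (19 and 2) and ribosomal proteins (61 and 0). Cholesterol synthesis (9 of 24 higher, 11 lower, median -0.11, or 0.73 under library size scaling, camera adjusted p = 0.636), fatty acid synthesis (6 of 16 higher, 8 lower, -0.20, or 0.65, 0.527) and the nuclear respiratory chain (4 of 65 higher, 32 lower, -0.30, 0.0608) were not called. Under library size scaling the nuclear respiratory chain had 49 higher and 4 lower (median 0.54). It was called lower by camera under upper quartile scaling (camera adjusted p = 0.0473), with the GC and length trend removed (0.0106), without uncultured 1 (0.013), without physioxia 1 (0.00654), under limma-voom (0.00423) and with no low-count filter (0.00375).

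HIF targets had 25 of 40 higher and 10 lower in physioxia against uncultured cells (median 0.84, camera adjusted p = 8.15e-05; adjusted p = 0.477 with an estimated correlation). CA12 rose by 5.92 ± 0.16, NDUFA4L2 by 6.51 ± 0.25, NDRG1 by 2.37 ± 0.16 and PDK1, which restrains pyruvate oxidation, by 1.26 ± 0.17. Glycolysis genes had 14 of 18 higher and 4 lower (median 1.43, camera adjusted p = 3.34e-06; adjusted p = 0.103 with an estimated correlation). Cytoskeleton and matrix genes had 33 of 36 higher and 1 lower (3.31, 3.59e-24) and NF-kB targets 17 of 19 higher and 1 lower (2.46, 1.3e-07), CCL20 rising by 6.57 ± 0.22. Camera with an estimated correlation kept both calls. It did not keep those of NRF2 targets (18 of 22 higher, 2 lower, median 1.404, camera adjusted p = 1.37e-07; adjusted p = 0.0504 with an estimated correlation), p53 targets (11 of 16 higher, 3 lower, 1.18, 7.9e-05; adjusted p = 0.0504 with an estimated correlation) and ATF4 targets (15 of 25 higher, 6 lower, 0.52, 0.000103; adjusted p = 0.06 with an estimated correlation). Nor did it keep those of heat shock genes (12 of 12 higher, 0.95, 0.000232; adjusted p = 0.104 with an estimated correlation) and ribosomal proteins (60 of 67 higher, 0.69, 8.15e-05; adjusted p = 0.587 with an estimated correlation). HMOX1 rose by 4.29 ± 0.20, GDF15 by 4.63 ± 0.15 and RPS19 by 1.35 ± 0.14. Immediate early genes (7 of 16 higher, 5 lower, median 0.30, camera adjusted p = 0.1, or 0.0343 under library size scaling and 0.0436 without physioxia 2), metallothioneins (5 of 8 higher, 1 lower, 0.96, 0.204, or 0.0331 with no low-count filter), proliferation genes (12 of 21 higher, 2 lower, 0.79, 0.107, or 0.00735 with no low-count filter) and nuclear-retained RNAs (3 of 7 higher, 2 lower, 0.42, 0.212) were not called.

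Markers of other cell types divided in physioxia against uncultured cells. Macrophage markers had 4 of 14 higher and 5 lower (median -0.29, or 0.56 under library size scaling, camera adjusted p = 0.583), CD68 rising by 2.11 ± 0.11 while MARCO fell by 3.70 ± 0.28. Endothelial markers had 2 of 12 higher and 7 lower (median -2.01, camera adjusted p = 0.186, or 0.0336 under library size scaling), stellate markers 3 of 11 higher and 5 lower (-0.73, or 0.10 under library size scaling, 0.913). Cholangiocyte markers had 8 of 10 higher and 1 lower (2.34, 0.0816, or, called higher, 0.0403 without normoxia 1, 0.0394 without physioxia 2 and 0.0187 with no low-count filter), KRT7 by 6.32 ± 0.31. Lymphocyte markers had 3 of 10 higher and 2 lower, with a median of 0.56 but a mean of -0.63 and a downward camera direction (adjusted p = 0.316), IL7R rising by 1.68 ± 0.31 while IGKC fell by 6.23 ± 0.23. Red cell markers had 2 of 7 higher and 0 lower, with a median of -0.32, or 0.52 under library size scaling, but a mean of 0.18 and an upward camera direction (adjusted p = 0.945).

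Whether cultured cells lay nearer to uncultured cells in physioxia was asked of genes that differed both between culture and uncultured cells (12780 genes, 6693 higher and 6087 lower in culture) and between physioxia and normoxia. Of 2781 such genes 1249 (44.9%) had their physioxia mean nearer to the uncultured mean. Among the 1385 lowered by culture 759 (54.8%) were nearer in physioxia, and among the 1396 raised by culture 490 (35.1%) were. The share turned with the scaling, to 68.7% under library size alone (82.5% of the raised and 24.97% of the lowered genes). With the GC and length trend removed it was 47.3%, and the balance turned, with 50.5% of the raised and 44.2% of the lowered genes nearer in physioxia. Nearer in physioxia mostly means higher there for a gene lowered by culture, and lower there for a raised one. Of all genes called between the cultures 59.4% were higher, 19.57% under library size scaling and 48.11% with the trend removed. The shares move with that balance, so by themselves they show no recovery of either set. Over all tested genes, the root mean square log2 distance to the uncultured mean was 1.64 ± 0.029 in normoxia and 1.68 ± 0.020 in physioxia (SD, n = 3), a difference of 0.0405 (exact permutation test, two-sided, p = 0.2, where 0.1 is the smallest p that 3 against 3 allows). The Spearman correlation with the uncultured mean was 0.870 in normoxia and 0.868 in physioxia (exact permutation test, p = 0.5). Single genes lay on both sides. The levels of CYP3A4 (3010 CPM in uncultured cells, 217 in normoxia, 316 in physioxia) and POR (594, 153 and 390 CPM) were nearer to uncultured cells in physioxia, and that of PROX1 (268, 27.9 and 16.7 CPM) was nearer in normoxia.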

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

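The tests weighed in this part were chosen only after the result was seen, apart from the counts over other splits, the other scalings and the estimated correlation, which were planned before the data were examined. The explanations they are set against were all written after it. The lines drawn between fitting and not fitting (0.5 times the uncorrected size, 2 standard errors, a 95% interval over libraries) were set after the values were seen too.

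Of 17494 genes 57 differed from uncultured cells in opposite directions in the 2 cultures and also between the cultures, and 9 of them are among the named genes. Each is singled out because the change from uncultured cells differs between normoxia and physioxia, as tested by physioxia against normoxia (edgeR). Of these STAB1 had a log2 difference of 4.115, from -2.53 in normoxia to 1.59 in physioxia, each against uncultured cells. For VSIG4 it was 4.061 (-2.52 and 1.54), for TYROBP 3.611 (-2.23 and 1.38), for LAPTM5 3.51 (-1.60 and 1.91) and for IL7R 2.887 (-1.21 and 1.68). The call of STAB1 against uncultured cells in physioxia was lost without uncultured 1 (1.61) or uncultured 3 (1.55), with no low-count filter (1.63), under limma-voom (1.13) and with the trend removed (1.295), its fall in normoxia was lost under limma-voom (-2.55), and its difference was 3.25 without physioxia 2. The globin HBA2 had 3.55 (-2.78 and 0.78), and its rise against uncultured cells was lost without uncultured 1 (0.74), uncultured 3 (0.77) or physioxia 1 (0.68) and with the trend removed (0.23). The DNA demethylase gene TET2 went the other way with -1.401 (0.58 and -0.83), and so did VEGFA with -1.14 (0.37 and -0.77). The rise of VEGFA in normoxia was lost without uncultured 3 (0.29), normoxia 2 (0.34) or normoxia 3 (0.26), and its value in physioxia turned to 0.08 under library size scaling. The mitochondrial chaperonin gene HSPE1 had 0.5919 (-0.28 and 0.32), a call lost once the GC and length trend was removed (0.18). The fall of IL7R in normoxia was lost under library size scaling (-0.16). Against uncultured cells that scaling shifts the median of all genes by 1.06 in normoxia and 0.84 in physioxia. The falls of TET2 in physioxia (-0.83) and of HSPE1 in normoxia (-0.28) are smaller than these shifts. Their opposite directions therefore rest on the TMM scaling.

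Of 40 HIF targets 20 were lower and 3 higher in physioxia, the arm with 7% oxygen, than in normoxia (median -0.50, adjusted p = 0.37 by camera with an estimated correlation). A GC or length bias as the whole cause is excluded by the median after its removal, -0.492, since removal moved the difference between library medians by only 0.00 ± 0.04. That difference itself was -0.4985 before and -0.50 after removal. Its Welch 95% intervals over libraries, -1.141 to 0.1442 and -1.052 to 0.05164, both include 0. Scaling stays open, as the other scalings moved all genes up by at most 0.007547 and so could not have ended the fall. Dilution of hepatocyte RNA by other cells would lower plasma protein genes alike, but their median was 0.4235, or 0.2486 with the trend removed. A rise of these genes for another reason could hide a dilution, so this does not rule it out. A biological explanation, lower HIF activity in the physioxia cultures, was not tested, and oxygen at the cells was not measured in the files used here.

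Of nuclear genes of the respiratory chain 25 of 65 were higher in physioxia, and of cytosolic ribosomal proteins 21 of 67 (adjusted p = 0.487 and 0.49 by camera with an estimated correlation). Removal of the GC and length trend took the median of the nuclear respiratory chain list from 0.35 to 0.09623 with its call kept (camera adjusted p = 0.00762; adjusted p = 0.386 with an estimated correlation), and that of the ribosomal list from 0.31 to 0.04 with its call lost (0.206), so whether a GC or length bias is the whole cause stays open. For the mitochondrially encoded list the median went from 0.67 to 0.376 and the list was still called higher (camera adjusted p = 1.62e-11; adjusted p = 0.142 with an estimated correlation). Over all its members the difference between library medians went from 0.71 ± 0.15 to 0.4342 ± 0.052, which excludes the trend, as fitted on nuclear genes, as the whole cause, while a bias of mitochondrial transcripts alone stays open. Whether the trend is technical or lies in the cells was not decided, and physioxia 1 leaned along it against its replicates.

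Of the markers of macrophages 12 of 14 were higher in physioxia, of lymphocytes 4 of 10 and of red cells 7 of 7 (camera adjusted p = 0.0852 with an estimated correlation for each list). A lower share of hepatocytes would raise every other cell type alike, but the median of the stellate list was 0.2386, and of the cholangiocyte list -0.54, against 2.57 for macrophages. The endothelial list went with the macrophages (median 1.66, 5 of 12 higher, 0 lower, camera adjusted p = 0.00383). The cholangiocyte list is a weak gauge of cell share, as it rose in normoxia against uncultured cells (median 3.175). The lists were thus not raised alike, but a lower share as part of the cause stays open. More of the macrophages of the vial, unchanged, is excluded, since 11 of 14 markers lay over 2 standard errors from the list's median ratio of physioxia to uncultured cells, from CD5L (-5.73) to CD68 (2.11), or to VSIG4 (1.54) with CD68 set aside. A change in those cells, such as better survival together with a changed state, was not tested. For red cells 3 of 7 markers lay apart in that way, from HBD (-0.80) to HBA1 (2.01), which decides nothing.

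Other splits of the same samples were counted as planned before the data were examined. In physioxia against normoxia 1 of 10 splits, the real one, called as many genes as 3442, and the highest other called 0. In normoxia against uncultured cells it was 1 of 10 (12065, highest other 0), and in physioxia against uncultured cells 1 of 10 (12309, highest other 0), so none of these can go under 0.1. In culture against uncultured cells it was 1 of 84, with 11868 genes in a model of 2 groups and at most 2 in any other split, which excludes a random split of the samples as the source.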

How the results depend on the processing

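Among the settings given here, the removal of the GC and length trend, the same without physioxia 1, and the analysis without other cell types' markers were chosen only after results were seen. The count of genes changed, physioxia against normoxia was 3442, and 153 against a change of at least 1.5-fold, a stricter question by construction. It was 1416 at an adjusted p under 0.01, also stricter by construction, 2118 with the trend removed, over fewer genes, and 2262 with it removed and physioxia 1 left out. Leaving out 1 library gave from 1563 (without normoxia 2) to 3813 (without physioxia 3), with fewer samples. DESeq2 called 3750 and limma-voom 3901. Counts against uncultured cells kept within 1.5 times of their value under every setting not named here.

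The HIF list (median -0.502) was not called by camera with a correlation estimated from these data (adjusted p = 0.37). That estimate was 0.476, against the preset 0.01. With estimated correlations camera called no list in physioxia against normoxia, and its lowest adjusted p was 0.0852. Nor was the HIF list called by fry (adjusted p = 0.054), and why was not tested. In physioxia against normoxia fry also did not call the nuclear respiratory chain, periportal and metallothionein lists (adjusted p = 0.0656 each). Camera with the preset correlation called all of these. The same held for the ribosomal and immediate early lists (fry adjusted p = 0.0966 each) and the cytoskeleton list (0.0972). Every other list that camera with the preset correlation called in this comparison was called by fry too. Some values turned their sign. The ribosomal list went to -0.01085 with the trend removed and physioxia 1 left out, and ACTB to -0.3158 with the trend removed, and the cause was not tested. Against uncultured cells in physioxia VEGFA went to 0.07648 and ANKRD37 to 0.8278 under library size scaling, which by construction shifts all genes. The share of genes nearer to uncultured cells in physioxia went from 44.9% to 68.69% under library size scaling for the same reason, and from 43.08% to 48.69% as 1 library was left out. The cultures' difference in distance to the uncultured mean went from 0.0405 to 0.002603 over genes of at least 10 CPM, where fewer genes enter, and from 0.0283 to 0.0569 as 1 library was left out. Of the named genes 57 lost their call in physioxia against normoxia under at least 1 setting, 9 in normoxia against uncultured cells and 5 in physioxia against uncultured cells.

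Replicate numbers do not pair the samples: of 9 pairs with the same number 0 had a correlation over 0.1 (from -0.073 to 0.0767), and 1 of 9 samples correlated best with its own number. With a replicate block 2986, 11819, 12023 and 12540 genes were called in physioxia against normoxia, normoxia against uncultured, physioxia against uncultured and culture against uncultured cells, and 45.9% were nearer. Under the block the cholangiocyte list was not called in physioxia against normoxia (camera adjusted p = 0.0505) and was called higher in physioxia against uncultured cells (0.0352). Depth limits the rare genes, since a library with 0 counts allows up to 0.0614 to 0.145 CPM.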

Other observations

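Both gene lists in this part, and FKBP5 and ZBTB16, were chosen only after values were seen. FKBP5, which binds the glucocorticoid receptor complex, rose from 90.7 to 185 CPM between normoxia and physioxia (log2 1.03 ± 0.13, n = 3), and ZBTB16 from 37.2 to 96.5 CPM (1.37 ± 0.14). If glucocorticoid signalling were stronger in physioxia, other targets would be higher together. Of 6 others 2 were higher and 0 lower, PER1 by 0.50 and TSC22D3 by 0.37, with a median of 0.3085 (camera adjusted p = 0.0786 over the 2 lists), which decides nothing.

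CYP1A1 and CYP1A2, targets of the aryl hydrocarbon receptor, were higher in physioxia (log2 1.92 ± 0.54 and 1.35 ± 0.18). CYP1A1 lost its call under 11 settings, among them the removal of the GC and length trend (1.67, adjusted p = 0.0801, edgeR), any single uncultured library left out and no low-count filter. Of 3 tested other targets 1, CYP1B1, was higher (4.21 to 13.7 CPM), and the median was -0.09466 (camera adjusted p = 0.228 over the 2 lists), which decides nothing either.

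The 20 most abundant genes took 36.4% of the counts in uncultured cells, 18.2% in normoxia and 23.8% in physioxia. Genes with at least 1 count numbered 22469 to 23800 in uncultured libraries, 24691 to 25442 in normoxia and 22404 to 23575 in physioxia. In physioxia 1 mitochondrial ribosomal RNAs took 11.3% of the counts.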
